A study of Homo sapiens with 8 samples.

How the data were processed

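Total RNA of wild-type and ALAS1-KO HEK293T cells was made into small RNA libraries, with 4 samples per genotype. Per the labels' protocols, the RNA received spike-ins and then a 3' linker, the ligated products were selected on a denaturing gel by size, a 5' adaptor was ligated, and the products were reverse transcribed, amplified by PCR and sequenced as single reads. The protocol names no molecular identifiers, so reads are not independent molecules, and counting intervals cover counting error only. The submitters' processing notes name cutadapt, limma and the genome build hg38. The aligner, the counting program, the tool versions and the miRNA annotation release are not given in the sources used here.

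The deposited values are whole-number counts of reads per mature miRNA, one file per sample, with no normalization. Each file listed 2657 entries, of which 2652 were miRNA names and 5 were summary lines. The summary lines (aligned outside the miRNAs, ambiguous, low alignment quality, unaligned, aligned to several places) stayed out of library sizes and tests. Reads outside the miRNAs were 92.3% of wild-type and 56.0% of knockout reads, and unaligned reads were 4.64% and 9.03%. The line for reads aligned to several places was 0 in every library although miRNAs with several identical hairpin copies had counts, so how such reads were assigned is unknown. Close relatives such as the let-7 members, miR-17, miR-20a and miR-106a, or miR-19a and miR-19b, can exchange reads, and their separate values are uncertain to that extent. Entries that overlap transfer or ribosomal RNA can hold fragments of those RNAs.

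Library sizes were the sums over miRNA entries, 433074 to 534900 in wild-type and 4110728 to 5207067 in knockout libraries. At this depth the exact (Clopper-Pearson) 95% binomial interval of the miRNA share in a single library is narrow, for example 2.94% to 2.96% in wild-type replicate 4. The wild-type libraries are the shallower ones for miRNAs and limit the tests of scarce miRNAs. Folds against a group with a count of 0 were computed against a floor of 3 counts over the group, and given as lower bounds.

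Differences were tested in R 4.3.3 with edgeR 4.0.16. Entries were filtered with filterByExpr (761 kept, holding 99.9% of counts), scaled with TMM, and tested with glmQLFit and glmQLFTest for genotype alone, with Benjamini-Hochberg adjustment and a threshold of 0.05. TMM factors were 0.728 to 0.757 in wild-type and 1.31 to 1.43 in knockout libraries. Normalised values are CPM of the TMM-scaled library size, with the mean and SD of 4 libraries. Standard errors of log2 fold changes were taken from the fold change and its F statistic. Arm ratios were log2 of 5p over 3p counts with a pseudocount of 0.5, for hairpins with both arms past the filter and with copies of a hairpin summed, and were tested with limma 3.58.1 with an intensity trend. Lists of at least 3 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Values per library were compared with an exact two-sided permutation test over the 70 assignments, whose smallest p is 0.0286. The 7 such comparisons form one family, and each has a Benjamini-Hochberg adjusted value of 0.0286. For equal depth, libraries were thinned without replacement to 433074 counts, and the mean of 20 draws was used.

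The groups came from the sample titles. Except where stated below, the tests, the 26 lists, the alternatives and the rule for naming miRNAs were set before the data were examined. The rule names the 10 largest changes in each direction among miRNAs past the threshold, with at least 100 CPM and no overlap between groups; the 8 most abundant miRNAs; up to 4 abundant members of each list as examples; the 6 hairpins with the smallest adjusted p for the arm ratio; and every tested member of lists with fewer than 6 tested members. The rule as set said lists of fewer than 6 members, which was read as fewer than 6 tested members. A miRNA that meets several parts counts under each. The comparisons per sequenced read, the thinned knockout libraries and the settings that use the likeness of knockout libraries were added after the data were seen. The permutation tests of the shares of miRNA, outside and unaligned reads were not among the tests set beforehand. Scaling by spike-ins was planned and not run, as all entries used here were miRNA names or summary lines.

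Hairpin positions were taken from GENCODE release 29 on GRCh38, the assembly also called hg38, and 741 of 761 tested miRNAs were matched by name to a hairpin gene. Mature arm positions within hairpins were not used here. GC content was that of the hairpin.

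The procedure was tested on simulated data for ALAS1-KO against WT, with counts of 761 miRNAs drawn from the real means and library sizes. It recovered 56.1% of 66 miRNAs changed by a log2 fold of 0.5, 83.6% of 67 changed by 1 and 94.0% of 67 changed by 2, and 4.88% of its calls were of miRNAs left unchanged. For arm ratios it recovered 32 of 39 changed hairpins among 208, with 1 false call. For lists it recovered 3 of 3 among 22 with 0 false calls. Simulated means were pooled over all 8 libraries, and libraries were drawn independently. For single miRNAs about as many were raised as lowered, without regard to abundance. The real changes followed abundance and the knockout libraries were alike in pairs, so these rates need not hold for the real data. The alternatives were RLE scaling, library totals, DESeq2 1.42.0, limma-voom, no filter, a filter at a mean of 10 CPM, a block for the replicate number, leaving out each library, another pseudocount, another count minimum, another number of abundant miRNAs and the median in place of the pooled minor-arm share.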

Results

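Small RNA libraries were compared between HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen, and HEK293T cells in which ALAS1 had been knocked out. ALAS1 encodes aminolevulinate synthase 1, the enzyme that starts heme synthesis in most cells, and the series asks whether ALAS1 takes part in the control of small RNAs. There were 4 wild-type and 4 ALAS1-KO libraries, each with a count for every mature miRNA. ALAS1 messenger RNA was not analysed here, because a small RNA library does not measure it, so the counts do not check the knockout itself. The libraries held 14691506 to 17679271 reads in the wild-type group and 11519089 to 15618339 in the knockout group. Of these, 433074 to 534900 per wild-type library and 4110728 to 5207067 per knockout library were counted to miRNAs. The labels call the RNA samples biologically independent but do not state how many knockout clones they came from, so p-values measure the spread between these samples only.

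The share of all reads that were counted to miRNAs was 11.5 times as high in ALAS1-KO cells. It was 3.04% ± 0.139 (SD, n = 4) in wild-type libraries and 34.9% ± 1.16 (SD, n = 4) in knockout libraries, with no overlap (exact two-sided permutation test, p = 0.0286, the smallest that 4 against 4 can give). Reads aligned outside the annotated miRNAs made up the difference, with 92.3% ± 0.283 of wild-type and 56.0% ± 0.600 of knockout reads (exact permutation p = 0.0286, n = 4 per group). Unaligned reads were 4.64% ± 0.286 and 9.03% ± 0.688 (exact permutation p = 0.0286, n = 4 per group). Counted per sequenced read, a comparison added after the data were seen, 750 of 761 tested miRNAs were higher in the knockout and 8 were lower by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The median log2 fold change per sequenced read was 4.50, and let-7a-5p, an abundant member of a differentiation-linked family, stood at 3.86. A share of reads does not separate more miRNA from less of the other RNA, and the labels do not say whether both genotypes were size-selected together. Counts of the spike-in RNAs named in the protocol were not used here.

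**Figure D1:**
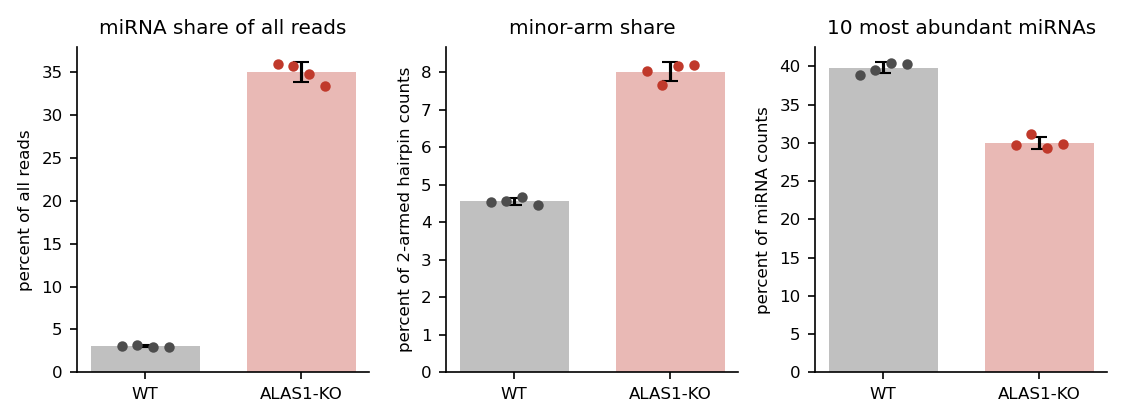
Per-library miRNA share of all reads, minor-arm share of the counts of 2-armed hairpins, and share of miRNA counts held by the 10 most abundant miRNAs, in percent. Points are libraries, bars are means and error bars are SD of 4 libraries per group. The miRNA share was 3.04% in wild-type and 34.9% in ALAS1-KO libraries.

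Within the miRNA pool, the most abundant miRNAs of HEK293T cells took a smaller part in the knockout and many scarce ones a larger part. After TMM scaling, which sets the typical miRNA near no change, miR-16-5p, a repressor of cyclins and BCL2, fell from 76525 ± 1884 CPM in wild-type to 21911 ± 1301 CPM in knockout libraries (SD, n = 4) with a log2 fold change of -1.80 ± 0.0518 (SE). The other 7 most abundant miRNAs were lower too, namely miR-17-5p (-0.99), miR-20a-5p (-1.01), miR-18a-5p (-1.16), miR-19b-3p (-1.50), miR-19a-3p (-1.17), miR-221-3p (-1.65) and miR-15a-5p (-1.41). All 8 had adjusted p of at most 1.71e-09 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4 libraries per group), and all 8 were also lower with library totals (log2 -0.95 to -0.13) but higher per sequenced read (log2 2.57 to 3.39). The 10 most abundant miRNAs together held 39.8% ± 0.709 of wild-type and 30.0% ± 0.756 of knockout counts (exact permutation p = 0.0286, n = 4 per group). At equal depth, 931 ± 12.4 miRNAs were detected in wild-type and 1089 ± 15.5 in knockout libraries (exact permutation p = 0.0286, n = 4 per group).

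Among miRNAs of at least 100 CPM on average, those with the largest falls were miR-4454, an entry that overlaps transfer RNA fragments, and miR-153-3p, a neuronal miRNA whose hairpins lie in introns of PTPRN and PTPRN2. miR-4454 went from 1119 ± 327 CPM in wild-type to 68.7 ± 2.40 CPM in knockout libraries (SD, n = 4) (log2 fold change -4.03 ± 0.173 (SE), adjusted p = 5.09e-11), and miR-153-3p from 1619 ± 115 CPM in wild-type to 154 ± 13.7 CPM in knockout libraries (SD, n = 4) (log2 fold change -3.39 ± 0.0883 (SE), adjusted p = 7.20e-13), both by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The remaining falls were those of miR-138-5p (-1.67), a miRNA of neurons, miR-221-3p, miR-5100 (-1.53), another entry that overlaps other RNA, miR-16-5p, miR-19b-3p, miR-15b-5p (-1.49), miR-106b-5p (-1.47) and miR-32-5p (-1.44), encoded in an intron of TMEM245. These 10 miRNAs were lower with library totals as well, by log2 -3.16 to -0.58, and higher per sequenced read, by 0.36 to 2.94.

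The largest rise above that level was that of miR-1269b, from 94.0 ± 26.5 CPM in wild-type to 332 ± 31.7 CPM in knockout libraries (SD, n = 4) (log2 fold change 1.81 ± 0.149 (SE), adjusted p = 8.92e-08, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). It was followed by let-7a-3p (1.51), the minor arm of let-7a, miR-33a-3p (1.26), from an intron of the sterol regulator SREBF2, and miR-200c-3p (1.24), an epithelial miRNA that represses ZEB1. Then came miR-499a-5p (1.19) from an intron of the myosin gene MYH7B, miR-20b-5p (1.17), miR-486-5p (1.14) of red cells and muscle, miR-181a-3p (1.13), miR-3065-5p (1.12) and miR-92a-1-5p (1.08). In GRCh38 the miR-1269b hairpin lies on chromosome 17 at 12917268 to 12917342, with no host gene found on its own strand. The other strand was not searched. The miR-153 hairpins lie at 219294111 to 219294200 of chromosome 2 and 157574336 to 157574422 of chromosome 7. The miR-16 hairpins lie in an intron of DLEU2 (chromosome 13, 50048973 to 50049061) and in an intron of SMC4 (chromosome 3, 160404745 to 160404825), and the single mature sequence does not tell these copies apart.

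**Figure D2:**
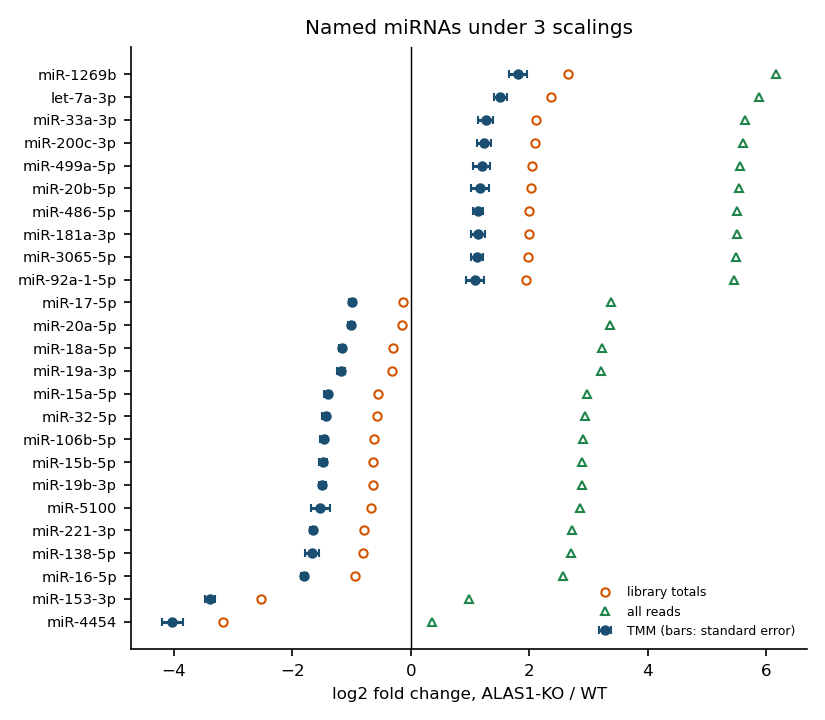
Log2 fold change of the miRNAs named for size of change or abundance, ALAS1-KO over WT, under TMM (filled, bars are SE), library totals (open circles) and all reads (triangles), from 4 libraries per group. miR-16-5p lies at -1.80, -0.95 and 2.57 in turn.

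In all, 186 of 761 miRNAs were higher and 163 lower in ALAS1-KO cells (edgeR, 4 libraries per group), and 151 of these changed at least 2-fold. The groups did not overlap in 340 of all 761 tested miRNAs, or 44.7%, where chance gives 2.86%, and in 317 of the 349 called. With TMM, direction followed abundance above 1000 CPM. All 25 miRNAs above 10000 CPM were lower (median log2 fold change -1.11), and 65 of 110 between 1000 and 10000 CPM were lower against 11 higher. Of the 25, miR-10a-5p was called higher with library totals (0.26). Between 100 and 1000 CPM 67 of 168 were higher and 30 lower, and between 10 and 100 CPM 84 of 284 were higher and 36 lower. Below 10 CPM 24 of 174 were higher and 7 lower. The medians of these 3 lower ranges were close (0.21, 0.29 and 0.31). Scaling set where 0 fell. Library totals raised the median log2 fold change of all tested miRNAs by 0.85, giving 563 higher and 55 lower (91.1% of calls higher against 53.3% with TMM), and all reads raised it by 4.34. All reads gave 750 higher and 8 lower. Each raise was nearly the same for every miRNA. A rise with TMM is therefore bound to recur with both, and lends no separate weight.

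**Figure D3:**
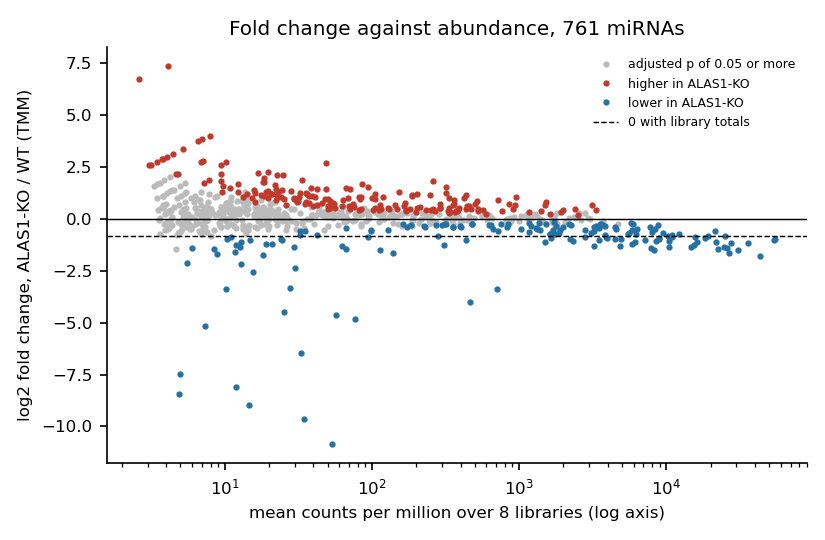
Log2 fold change of 761 miRNAs (TMM, ALAS1-KO over WT) against their mean CPM over 8 libraries on a log axis, one point per miRNA, coloured by call. The 25 miRNAs above 10000 CPM all lie below 0, with a median of -1.11 that becomes -0.25 with library totals (0 on that scale is the dashed line).

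In 3 clusters that carry much of the miRNA of this line, more members were lower than higher after TMM scaling but not with library totals, and camera called these lists with a preset correlation but not with an estimated one. In the miR-17~92 cluster, an oncogenic polycistron in MIR17HG on chromosome 13 (91350605 to 91351391), 6 of 12 measured members fell and 3 rose, against 5 lower and 6 higher with library totals and 12 higher per read. Its minor arm miR-92a-1-5p rose. Over the 10 members of a single locus, a set tested after the result was seen, 4 were lower and 3 higher. That set leaves out miR-19b-3p and miR-92a-3p, and camera did not call it (adjusted p = 0.195 over 20 clusters, and 0.689 with an estimated correlation). The miR-106b~25 cluster in an intron of MCM7 (chromosome 7, 100093560 to 100094074) had 4 of 6 lower and 1 higher, against 2 lower and 3 higher with library totals and 6 higher per read. There miR-106b-5p, miR-93-5p (-0.91) and miR-25-3p (-1.38) fell, while miR-93-3p stood at 0.05. The X-linked cluster of miR-221 and miR-222 (45746157 to 45747124), whose miRNAs repress the cell cycle inhibitor CDKN1B, had 3 of 4 lower, against 1 lower and 1 higher with library totals and 4 higher per read. Here miR-222-3p (-0.82, but 0.04 with library totals) and miR-222-5p (-0.98) fell with miR-221-3p, and miR-221-5p stood at -0.05. The counts adjusted over the list alone were the same for these 3 lists.

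The miR-181 family, known from lymphocyte development, went the other way, with 8 of 9 members higher and 9 adjusted over the list alone, and 9 higher with library totals and per read. Examples are miR-181a-5p (0.41), miR-181b-5p (0.65), miR-181d-5p (0.23) and miR-181c-5p (0.46). Set against all other miRNAs (camera, preset correlation of 0.01, Benjamini-Hochberg over 22 lists), adjusted p was 0.0125 for miR-17~92, 0.00772 for miR-106b~25, 0.00123 for miR-221 with miR-222 and 0.0234 for miR-181. None of the 4 calls held with the correlation estimated from the data, and adjusted p = 0.333, 0.143, 0.143 and 0.333 with an estimated correlation, in that order. With 1 library left out at a time, only miR-221 with miR-222 was called every time. Without knockout replicate 1 or 3 the other 3 lists lost the call (adjusted p = 0.0549 to 0.0637), and without replicate 4 miR-17~92 did (adjusted p = 0.0802). With library totals the call ended for the 3 lists that fell (adjusted p = 0.878, 0.460 and 0.340).

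**Figure D4:**
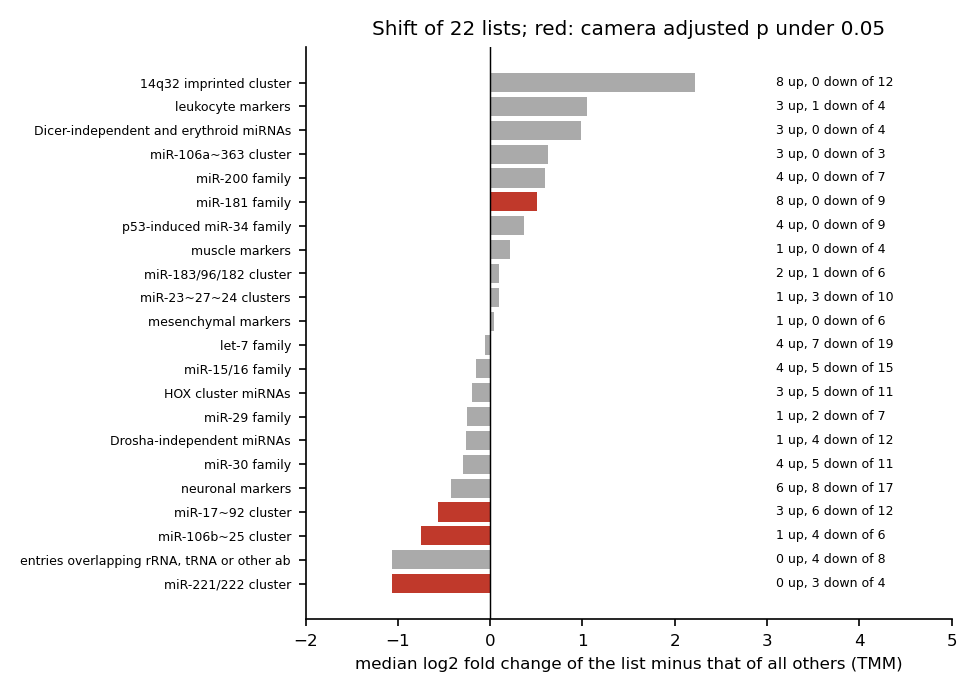
Median log2 fold change of each of 22 lists minus that of all other miRNAs (TMM, ALAS1-KO over WT), with the members called higher and lower at the right, from 4 libraries per group. Bars in red passed camera with the preset correlation, and none of these passed with an estimated one. With library totals the calls of members move upward, as in the let-7 family, where 7 lower and 4 higher became 1 lower and 15 higher.

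Other families of this line were split between members, and camera did not call them. Of the let-7 family, 7 of 19 were lower and 4 higher (5 higher and 7 lower adjusted over the list alone), against 1 and 15 with library totals, with let-7f-5p at -1.04, let-7a-5p at -0.51, let-7g-5p at -0.87 and let-7e-5p at 0.27. The miR-15/16 family had 5 of 15 lower and 4 higher, against 3 and 12 with library totals. Its lower members included miR-424-5p (-0.67), which was higher with library totals (0.19). Of the miR-30 family, 5 of 11 were lower and 4 higher, against 0 and 9 with library totals, with miR-30e-5p at -0.81 and miR-30a-5p at -0.21. In the HOX clusters, which pattern the body axis, 5 of 11 were lower and 3 higher (4 adjusted over the list alone), against 1 and 8 with library totals. There miR-196b-5p (-1.12, and -0.27 with library totals) was lower with both scalings, miR-196a-5p (-0.89) lost its call with library totals (-0.03), and miR-10b-5p (-0.31) was then higher (0.55). The miR-232724 clusters had 3 of 10 lower and 1 higher, against 1 and 9 with library totals, with miR-24-3p at -0.99. The miR-29 family, which targets collagens, had 2 of 7 lower and 1 higher, against 1 and 5 with library totals, with miR-29b-3p at -1.34 and miR-29c-3p at -0.71. The sensory cluster of miR-183, miR-96 and miR-182 had 1 of 6 lower, miR-96-5p at -0.98, and 2 higher, against 1 and 5 with library totals. Of the members given with negative values here, let-7a-5p, miR-30e-5p, miR-30a-5p and miR-29c-3p also stood above 0 with library totals. Every measured member of these 7 lists was higher per sequenced read. Adjusted over the list alone the counts of these lists were the same except where given.

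Of the X-linked cluster from miR-106a to miR-363, a relative of miR-17~92, all 3 measured members rose after TMM scaling. These were miR-106a-5p (0.78), miR-18b-5p (0.47) and miR-20b-5p (1.17), with camera adjusted p = 0.0797, and adjusted p = 0.419 with an estimated correlation. Library totals and all reads raise every value, so the rises there were bound to follow. The epithelial miR-200 family had 4 of 7 higher and 0 lower, among them miR-200c-3p, miR-141-3p (0.46) and miR-200b-3p (1.36, on 1 to 9 counts per wild-type library), and 7 higher with library totals and per read. The p53-induced miR-34 family had 4 of 9 higher and 0 lower (4 and 1 adjusted over the list alone), with miR-34a-3p at 0.51 and miR-449a at 0.39, while miR-34a-5p stood at -0.25 and was higher with library totals (0.60). All 9 were higher with library totals and per read. Of the 14q32 imprinted cluster, 8 of 12 tested members were higher (9 adjusted over the list alone), 11 with library totals and 12 per read, on 84 wild-type against 5604 knockout counts over all its entries, and 6 of the 8 had only 1 to 3 wild-type counts each. That sum was 3.88-fold higher after TMM scaling (95% counting interval 3.13 to 4.87). Its member miR-376c-3p rose by 1.88 (on 3 to 6 counts per wild-type library) and miR-377-3p by 2.11 (on 1 to 4). Members with 1 to 3 wild-type counts passed the filter only through the knockout libraries, which favours higher values among the tested members. Camera called neither the miR-200 family (adjusted p = 0.115), nor the miR-34 family (adjusted p = 0.330), nor the 14q32 cluster (adjusted p = 0.0837, and adjusted p = 0.333 with an estimated correlation). The hypoxia-induced miR-210-3p was lower (-0.61, edgeR adjusted p = 7.98e-05) but higher with library totals (0.25) and per read (3.77). Pluripotency miRNAs and the C19MC cluster had 0 tested members, with 8 and 12 wild-type counts and 334 and 336 knockout counts in all.

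Of the markers of other cell types some members were higher and some lower, and camera called none of the lists tested. Of the erythroid list, 3 of 4 rose after TMM scaling, miR-486-5p, miR-486-3p (1.95) and miR-451a (1.13, matured without Dicer), while miR-144-3p stood at 0.31. Counts per wild-type library were only 1 to 3 for miR-486-3p and 1 to 6 for miR-451a. Of the leukocyte list, miR-142-3p (1.03) and miR-142-5p (1.36, on 1 to 5 counts per wild-type library) rose, as did miR-150-5p, which had 1 wild-type count (10.6-fold higher after TMM scaling, 95% counting interval 1.88 to 420.4). Its miR-146a-5p fell (-0.96, and -0.10 with library totals, but 3.38 per read). Of 4 muscle entries miR-499a-5p rose after TMM scaling, while miR-499a-3p (1.30), miR-1-3p (-0.44) and miR-133a-3p (-0.50) did not pass the test. Of 6 mesenchymal entries miR-199a-5p rose (1.64, on 1 to 5 counts per wild-type library), while miR-143-3p, miR-199b-5p and miR-199a-3p stood at 0.00, -0.10 and 0.07. All 6 were higher with library totals and per read. The endothelial miR-126-3p (-1.33) and miR-126-5p (-0.74) fell. With library totals miR-126-5p stood above 0 (0.12) but did not pass the test, and both were higher per read. Neuronal markers had 8 of 17 lower (9 adjusted over the list alone) and 6 higher, against 3 and 11 with library totals and 17 higher per read. Among the abundant ones, miR-218-5p (-1.39) and miR-7-5p (-1.11) were lower, also with library totals (-0.53 and -0.25), while miR-128-3p (-0.27) and miR-9-5p (-0.27) were lower but turned higher with library totals (0.59 and 0.59). Adjusted over the list alone the counts of the other lists of cell type markers were the same.

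Drosha-independent miRNAs had 4 of 12 lower and 1 higher, against 0 and 8 with library totals and 12 higher per read. miR-320a-3p stood at -0.30, miR-484 at -0.18 and the mirtron miR-1226-3p at -0.57, all above 0 with library totals. Of 8 entries that overlap ribosomal, transfer or other abundant RNA, 4 were lower and 0 higher, against 3 and 2 with library totals and 8 higher per read. Besides miR-4454 and miR-5100, miR-7977 fell (-1.29) and miR-4485-5p stood at 0.07. Summed over the list these entries held 1175 CPM in wild-type and 448 CPM in knockout libraries, before TMM scaling, a fall carried by miR-4454, without which they held 345 and 356 CPM. Camera called neither the Drosha-independent list nor the overlapping entries (adjusted p = 0.0837 for the last, and adjusted p = 0.333 with an estimated correlation).

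The balance between the arms of a hairpin, which no scaling of libraries can move, shifted toward the minor arm in ALAS1-KO cells. A hairpin yields a 5p and a 3p strand, of which the major arm is mostly kept in Argonaute and the minor arm mostly lost. The minor-arm share of all counts from 2-armed hairpins was 4.56% ± 0.0962 (SD, n = 4) in wild-type and 8.01% ± 0.248 (SD, n = 4) in knockout libraries (exact permutation p = 0.0286). For miR-16 the minor arm went from 0.631% ± 0.0420 to 2.20% ± 0.247 of the hairpin's counts, and for miR-15b from 7.22% ± 0.449 to 19.5% ± 1.04 (SD, 4 libraries per group). For miR-221 it went from 3.01% ± 0.143 to 8.64% ± 0.766, for miR-18a from 2.89% ± 0.271 to 7.57% ± 0.386, for miR-19b from 3.14% ± 0.313 to 8.56% ± 0.447 and for miR-25 from 0.237% ± 0.0278 to 0.909% ± 0.0908. The log2 ratio of minor to major arm rose by 1.47 (miR-18a) to 1.92 (miR-25) in these 6 hairpins, each with adjusted p = 4.7e-07 (limma with Benjamini-Hochberg adjustment). Of 225 hairpins with both arms past the filter, 89 changed their arm ratio, 82 toward the minor arm and 7 toward the major arm. One of these, miR-10394 toward the minor arm, had 2 knockout counts in all, so its ratio was set by the pseudocount, and 88 remain without it. With a pseudocount of 5 in place of 0.5, 137 hairpins were called. The larger pseudocount pulls wild-type ratios toward equal arms more than knockout ratios, because wild-type counts are lower, so depth alone can add calls. The direction of these calls is not given here, and their number adds no weight to the shift.

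**Figure D5:**
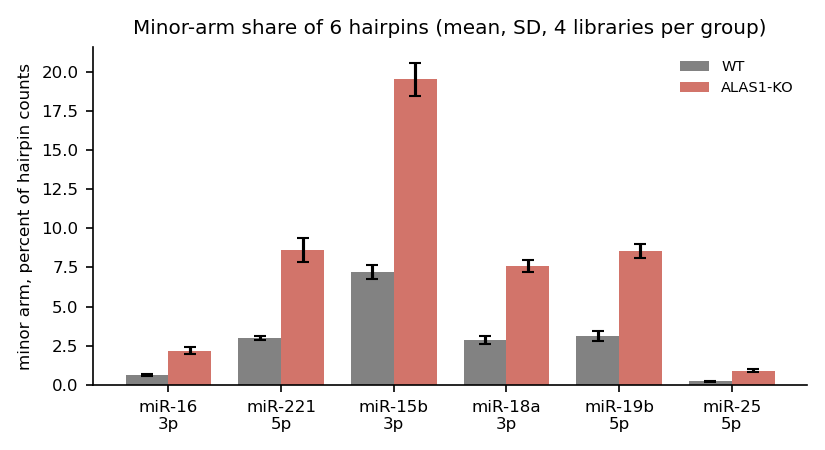
Minor arm as a percent of the hairpin's counts in the 6 hairpins with the smallest adjusted p for the arm ratio. Bars are means and error bars SD of 4 libraries per group. The miR-15b minor arm made up 7.22% in wild-type and 19.5% in ALAS1-KO libraries.

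The knockout libraries did not vary evenly among themselves. Replicates 1 and 3 were alike (chi-square per degree of freedom 1.80 over 957 miRNAs) and so were 2 and 4 (6.12 over 991) at their depth, against 33.5 to 36.2 between these pairs. The median absolute log2 difference over 303 miRNAs was 0.03 (1 and 3) and 0.06 (2 and 4) within pairs, 0.11 to 0.14 between them and 0.11 to 0.17 between wild-type libraries, which have more counting noise. Each pair differed by more than counting noise, which does not show that its libraries are separate samples, and all 8 were kept as the labels give them. The exact permutation p-values above count every library as a separate unit. With each knockout pair as 1 unit, too few assignments would remain for a p below 0.05. Summing the counts within each knockout pair left 280 calls among 529 tested miRNAs in place of 349 among 761, of which 277 were shared with the same direction. Of the 128 named miRNAs, hairpins and lists, 115 kept their call status and 3 lost their call when the pairs were summed. The rest had no value under that setting, which tested fewer miRNAs.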

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

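The tests of depth, of scaling, of entries that overlap other RNA and of the depth of knockout pairs, and all counts of other splits, were chosen after the result was seen, while those of GC content and of arms at equal abundance were set before it.

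Against regrouping of the libraries, 5 of the 6 counts stood apart. Among the 35 ways to split the 8 libraries into 4 and 4, only 1, the real one, gave as many miRNAs higher (186, highest other 0), lower (163, highest other 0), changed at least 2-fold (151, highest other 0) or higher per sequenced read (750, highest other 0), or as many hairpins with a changed arm ratio (89, highest other 0). Every other split mixes the genotypes within its groups, so the genotype difference enters the spread and makes such calls unlikely. A share of 1 in 35 sets the real split apart if the 8 libraries are independent, but does not exclude chance. For the lists, 2 of the 35 splits gave as many (4, highest other 4), so chance cannot be excluded. With knockout libraries 1 and 3 kept together, and 2 and 4, only 7 splits remain, too few for a share under 0.05 for any of the 6 counts (highest other 0 for each).

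The abundant miRNAs, such as miR-16-5p and miR-17-5p, were lower and minor arms higher in the knockout. Hairpin GC content did not account for the fall of the abundant miRNAs, and the test of depth could not decide. Thinning at random keeps the expected share of each miRNA, so the gap was bound to stay near its size. The tests of depth and of GC measured only the gap between ranges of abundance. Hairpin GC is the same for both arms, so it could not test the shift between arms. With the knockout libraries thinned to the wild-type total the gap in median log2 fold change between miRNAs above 10000 CPM and those of 100 to 1000 CPM was -1.29, against -1.32 before, and with a trend on hairpin GC removed it was -1.31. Scaling cannot produce the median shift of 0.44 (log2) toward the minor arm within hairpins. A trend with abundance that is alike for both arms cannot be told apart from an effect on arms as such, since at 100 to 1000 CPM the 65 minor arms lay only 0.14 (log2) above the 79 major arms (permutation test, p = 0.290), between the bounds set for either reading. A difference in library preparation between the genotypes, for which the labels give no batch, and loss of ALAS1, which could alter how strands are kept, both stay open and were not tested.

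The miRNA share of reads was 11.5 times as high in the knockout. More fragments of other RNA in the wild-type libraries could lower that share with no change in miRNA. Entries that overlap other RNA would then stay at or below 0 per sequenced read, but their median log2 fold change was 3.44, from 0.36 (miR-4454) to 4.44 (miR-4485-5p), against 4.51 for all other miRNAs. Since these 8 entries lie between both bounds, and spike-in counts were not used here, less fragment RNA in ALAS1-KO cells, more miRNA in them and a different size selection of the libraries, for which the labels give no batch, cannot be told apart. Dilution alike for every miRNA does not by itself account for the 349 changes of composition.

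Knockout libraries 1 and 3, and 2 and 4, were close to each other, which could come from shared clones, cultures or library batches that the labels do not give. Depth did not account for it, since the pair with the largest difference in depth (2 and 4, 1.27-fold) had a chi-square per degree of freedom of 6.12, against 33.5 or more between pairs. Hairpin GC accounted for 1.99% of the variance of the difference between pairs over 300 miRNAs above 100 CPM. The largest differences were those of miR-30e-3p (log2 1.08 higher in 1 and 3) and miR-193b-3p (1.03), chosen after their values were seen. No biological explanation was tested, and the source of the pairing stays open.

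Of 214 groups of 4 libraries tested for a library far from the others, 8 had one, where chance gives about 10.7. In normalised CPM these were miR-3065-5p in wild-type replicate 4 (111.2, others 140.2 to 145.7), miR-25-3p in wild-type replicate 4 (22227, others 23473 to 23729) and miR-181d-5p in wild-type replicate 3 (465.5, others 528 to 537). The same held for miR-150-5p in wild-type replicate 4 (3.18, others 0) and miR-133a-3p in wild-type replicate 2 (22.9, others 12.5 to 14.3). Among knockout libraries they were miR-486-3p in replicate 1 (26.0, others 23.2 to 23.6), miR-7-5p in replicate 4 (10301, others 11154 to 11229) and miR-199a-3p in replicate 4 (21.5, others 17.6 to 17.7). The unaligned reads, which enter no miRNA count, made up 9.03% of knockout reads on average against 4.33% to 5.03% in wild-type libraries.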

How the results depend on the processing

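The settings that sum, select or thin knockout libraries, and all counts per sequenced read, were chosen after seeing the data. Of 2207 values of named miRNAs, hairpins and lists under alternatives, 30 turned direction with a call on at least 1 side, and another 59 changed sign with no call on either side. Of 153 values of the main results none turned, but many of these are counts of calls, which cannot turn direction. With library totals, whose construction adds 0.85 to the median, 563 miRNAs were higher, 55 lower and 389 changed at least 2-fold. Of the miRNAs named, 28 then turned positive (log2), of which miR-1-3p (0.41) and miR-133a-3p (0.36) were called under neither scaling, and 26 were called under at least 1, namely let-7a-5p 0.34, miR-424-5p 0.19, miR-30e-5p 0.043, miR-30d-5p 0.34, miR-30a-5p 0.65, miR-30c-5p 0.46, miR-10a-5p 0.26, miR-10b-5p 0.55, miR-27b-3p 0.48, miR-23b-3p 0.75, miR-27a-3p 0.16, miR-29c-3p 0.14, miR-29a-3p 0.62, miR-29c-5p 0.79, miR-222-3p 0.037, miR-221-5p 0.81, miR-183-5p 0.85, miR-34a-5p 0.60, miR-210-3p 0.25, miR-320a-3p 0.56, miR-484 0.68, miR-1226-3p 0.28, miR-128-3p 0.59, miR-9-5p 0.59, miR-199b-5p 0.75 and miR-126-5p 0.12. With no filter, 289 were higher, and, among those called on at least 1 side, miR-30a-5p (0.021), miR-183-5p (0.23) and miR-484 (0.051) turned positive; per sequenced read 1523 were then higher, as more were tested. With knockout libraries 2 and 4 only, miR-182-5p turned to -0.20. With the knockout thinned, 95 changed at least 2-fold, on 486 miRNAs left to test. Summed knockout pairs gave 5 lower per sequenced read. A pseudocount of 5 gave 137 arm ratio calls, and its construction can add calls, since it weighs more on the lower wild-type counts. With an estimated correlation 0 lists passed camera after adjustment and 2 had an unadjusted p below 0.05, while fry, which does not compare a list with the other miRNAs, called 18 (main setting: 4). Where no construction is named, the cause was not tested.

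Leaving out 1 library at a time gave 161 to 207 miRNAs higher, 137 to 143 lower, 102 to 176 changed at least 2-fold, 79 to 105 arm ratio calls, 5 to 9 lower per sequenced read and 1 to 7 lists. These settings also changed the filter, which kept 521 to 526 miRNAs without a knockout library and 937 to 941 without a wild-type one, against 761. The lists numbered 7 without any one of the wild-type libraries and 1 without knockout replicate 1 or 3; the lower miRNAs per read numbered 5 without knockout replicate 1 or 3. DESeq2 shared 329 and limma-voom 319 of the 349 calls, all in the same direction. With library totals 241 of the 349 were shared in the same direction and 62 were called in the opposite one. Libraries with the same replicate number did not deviate together (r = 0.34, 0.04, -0.18 and 0.17 across 303 miRNAs, which are not independent), so the numbers do not pair them. A block for the number gave 193 higher, 174 lower, 151 changed at least 2-fold, 90 arm ratio calls, 5 lists, and 750 higher and 8 lower per sequenced read. Libraries numbered 1 and 4 correlated best with their own number in the other genotype, and those numbered 2 and 3 did not. Wild-type depth limits the scarce miRNAs, of which 17 were called higher on 1 to 3 wild-type counts.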

Other observations

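The test of genomic clusters and the choice of the miRNAs in this part came after the result was seen. The cluster of miR-132 and miR-212 on chromosome 17 (2049908 to 2050380), whose miRNAs respond to neuronal activity through CREB, had 4 of 4 measured members higher in ALAS1-KO cells. These were miR-132-3p at 1.04 ± 0.107 (SE), miR-132-5p at 1.01, miR-212-3p at 0.95 and miR-212-5p at 1.33 (log2, TMM). Library totals, which raise every value, gave the cluster a median of 1.88. This cluster went against the abundant neuronal miRNAs such as miR-218-5p, which fell. The cluster of miR-191 and miR-425 on chromosome 3 (49020148 to 49020709) had 3 of 4 lower under TMM, with miR-425-5p at -1.06 and miR-191-5p at -0.72, but a median of 0.29 with library totals. The minor arm miR-191-3p rose (0.41). Of the testis-linked X chromosome miRNAs between the hairpins of miR-513c and miR-514a (147189704 to 147284728), 5 of 20 entries were tested and 5 were higher, 3 of them on at most 1 wild-type count. Those 3 passed the filter only through the knockout libraries, so the filter itself favours higher values among the tested entries. Of these miR-508-3p had 0 wild-type and 152 knockout counts, at least 2.95-fold higher against a floor of 3 counts over the group. miR-507 (1 against 120 counts, 6.98-fold, 95% counting interval 1.23 to 278) and miR-509-3p (1 against 107, 6.22-fold, 1.09 to 248) rest on 1 wild-type count each.

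Some scarce entries were nearly confined to wild-type libraries despite their lower miRNA depth. miR-4285 had 213 wild-type counts and 1 knockout count (3662-fold lower in the knockout after TMM scaling, 95% counting interval 650.2 to 145315), and miR-10394-3p had 135 and 2 (1161-fold lower, 315 to 9681). miR-3654 had 56 and 1, miR-3141 had 47 and 2, miR-4426 had 20 and 1, and miR-10394-5p had 19 and 0 (at least 109-fold lower). These 6 entries, with miR-9901 and miR-296-3p, are the 8 that were lower per sequenced read. Their falls on that scale were smaller than after TMM scaling, since all reads raised the median log2 fold change by 4.34. miR-4454 had nearly level counts per sequenced read (log2 0.36).

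That neighbouring hairpins move together was tested over 20 clusters of at least 4 measured miRNAs of a single locus within 10 kb. Camera called 2 of the 20 with the preset correlation, that of miR-221 and miR-222 (adjusted p = 0.00112) and miR-106b~25 (adjusted p = 0.00702), and neither with the correlation estimated from the data (adjusted p = 0.130 for both with an estimated correlation). That of miR-132 and miR-212 stood at adjusted p = 0.0501. Shared transcription may add to these shifts, but the test leaves that open. Minor arms lay above major arms of like abundance by 0.33 (log2) at 1000 to 10000 CPM (20 and 86 arms, permutation test p = 0.0322, adjusted 0.0967 over 3 ranges) and by 0.22 at 10 to 100 CPM (102 and 118 arms, p = 0.0989, adjusted 0.148), and arms are not independent replicates.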
